A study of Mus musculus with 8 samples.

How the data were processed

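RNA was measured on Affymetrix gene expression arrays from B-1a cells, a self-renewing B cell subset of the body cavities, sorted by flow cytometry from the peritoneal lavage of 5-week-old mice. Mutant mice (KO) carried a Cre recombinase allele active in B lineage cells and 2 loxP-flanked copies of the gene for PTIP, Paxip1. Control mice carried the same Cre allele with unmodified Paxip1. Per the labels, 29 KO and 22 control mice were divided into 4 biological replicate samples per genotype, so that each array is a pool of mice. RNA was extracted with a column kit, its integrity number was above 8 in the labels' protocols, and the labelled target carried biotin. How many mice went into each pool, their sex and the gates of the sort are not given in the sources used here.

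The deposited table holds log2 values of 41345 probe sets on 8 arrays. Per the submitters' processing notes, the authors used RMA, which corrects background, sets the arrays to 1 shared distribution and summarises the probes of a probe set on the log2 scale, and R 3.2.2. The package, the probe set annotation and the summarisation level are not given in the sources used here. The medians of the 8 arrays over all probe sets lay between 3.68 and 3.74, and the values ranged from 1.37 to 13.8. Quantile normalization of this kind removes any difference in total RNA, so a difference here is relative to the other genes of the array. RMA values flatten out near the background, so the fold of a gene that is dim in 1 group is understated. No probe set was declared present or absent. Arrays give no read depth, and their number limits the precision.

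Probe sets were named through the platform annotation. Of 25335 probe sets listed there, 23521 had exactly 1 gene symbol, 1814 had several and were not named, and 16010 probe sets of the deposited table were not listed and stayed unnamed. The gene identifiers of 23328 probe sets matched a RefSeq gene table of assembly GRCm38.p6, which was used for names, gene types and the order of neighbouring genes only. Where a gene had more than 1 probe set (1082 genes), the one with the highest mean over all arrays was kept, which left 22180 genes. No coordinates are given, because the annotation's build is not given in the sources used here.

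KO was compared with control on the log2 values with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default prior, two-sided, Benjamini-Hochberg adjustment over all 22180 genes, adjusted p under 0.05). A gene that passed is described as called. Errors are the SD of 4 pools or the standard error (SE) of the fit. Lists of genes were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the lists, and beside it with an estimated correlation, with fry, and by counts of called members. Of the 552 symbols written into 32 lists, 496 matched a tested gene; 30 lists with at least 5 measured members were tested. Members that did not match, Ighd, Lyn, Lck and Tcf7 among them, were not analysed here. The test, its threshold, the lists, the alternatives (apart from those named as later additions) and the rule for named genes were chosen before the data were examined. The rule named Paxip1, the 12 largest rises and the 12 largest falls among called genes whose groups did not overlap, leaving out predicted genes and clone names, and at most the 4 members with the smallest p of each list described. Other genes are named as chosen after their values were seen.

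Simulated data had the spread of the real arrays and 22180 genes. Of these, 50 each were changed by a known fold, all from above the median in mean value. The fit was tested on these data. In the comparison of 4 KO with 4 control arrays it recovered 54% of genes changed 1.5-fold, 86% of those changed 2-fold, 98% at 3-fold and 100% at 4-fold, with 9 false calls (5.06% of all calls). A simulated list of 20 genes shifted by 0.5 on the log2 scale was recovered, and 0 unshifted lists were called. Simulated genes varied independently of one another, whereas members of the real lists had estimated correlations of up to 0.787. This simulation therefore does not show how often camera calls unshifted lists of the real arrays at the preset correlation.

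Alternatives changed the choice of probe set, the genes tested, the scaling, the variance prior, the array weights, the threshold, a block for the replicate number and the list test, and left out each pool in turn. Added after the values were seen were a fit with the mean of the T cell markers as a covariate and a fit without KO pools 1 and 2. Each was run with the other choices unchanged.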

Results

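Peritoneal B-1a cells of 4 KO pools and 4 control pools were compared on 8 arrays, 1 array per pool. The design asks which transcripts depend on PTIP in B-1a cells, since Cre removes the floxed gene in B lineage cells. PTIP, the product of Paxip1, is a subunit of the histone H3K4 methyltransferase complexes built on MLL3 and MLL4 and a partner of the DNA break factor TP53BP1. Across genes, which are not independent replicates, Pearson's r lay between 0.990 and 0.993 among KO arrays, between 0.992 and 0.993 among control arrays and between 0.986 and 0.989 across genotypes. The number of arrays limits the precision of every value.

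Paxip1 itself was 6.36-fold lower in KO, at 4.38 ± 0.54 on the log2 scale against 7.05 ± 0.13 in control (SD, n = 4 pools each). The difference was -2.67 (SE 0.22, limma, adjusted p = 9.96e-05), and the KO pools lay between 3.58 and 4.79, all below the lowest control pool at 6.87. A second Paxip1 probe set fell by 3.24. An exact two-sided permutation test over the 70 assignments of the arrays gave p = 0.0286, the smallest this design allows. Where either probe set lies relative to the deleted part of the gene is not given in the sources used here.

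Loss of Paxip1 went with 797 called genes, 331 of them higher and 466 lower in KO, or 3.59% of the 22180 tested. The falls included the urokinase receptor Plaur, the cytokine Il18, the TNF receptor family member Tnfrsf8 (CD30) and the integrin chain Itgam (CD11b). The rises included Rgs18 and Rgs13, regulators of G protein signalling, the ectoenzyme Bst1, the receptor Il9r and the fatty acid receptor Cd36. Of the called genes, 45 rose and 75 fell at least 2-fold, 3 rose and 9 fell at least 4-fold, and 706 were protein-coding. In 785 of the 797 the 4 KO values did not overlap the 4 control values, as was so for 10.5% of all tested genes against 2.86% by chance. The first principal component held 33.9% of the variance and separated the genotypes, with KO scores of at least 0.22 and control scores of at most -0.30. Leaving out 1 pool moved the total by over 1.5 times for KO pool 2 (498 genes) and for control pools 2, 3 and 4 (530, 497 and 479). The rises then numbered 196, 209, 205 and 205, and 219 without KO pool 4; the falls numbered 302 without KO pool 2, 292 without control pool 3 and 274 without control pool 4. Of the added alternatives, the T cell marker mean as a covariate left 312 called genes, 274 of them among the 797, and omission of KO pools 1 and 2 left 320, 289 of them shared. Without moderation of the variance 303 were called, 267 of them shared. Most single calls were therefore lost in each of these fits. Each has less power, through fewer arrays, a covariate that differed by 1.09 between the groups, or no moderation. A lost call thus need not mean a smaller difference. With the covariate that of Mall went from -2.13 to -2.03, while that of Klrd1 shrank from 1.83 to 0.69.

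**Figure D1:**
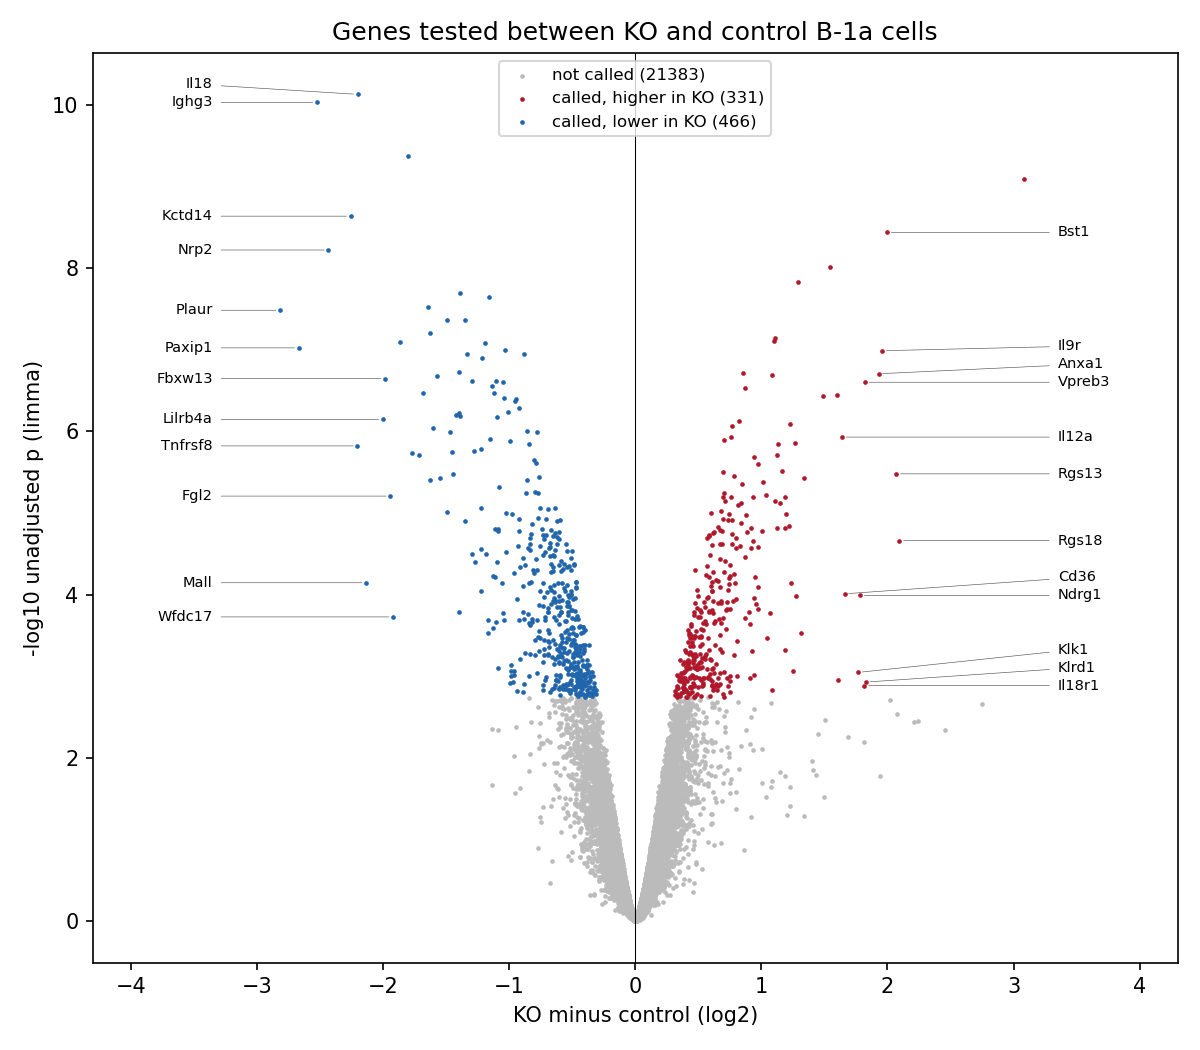
Difference between KO and control (log2, horizontal) against the unadjusted p of limma (-log10, vertical) for 22180 genes, 1 point per gene, with 331 called genes higher in KO in red, 466 lower in blue and the genes named by the rule labelled. Il18 and Ighg3 have the smallest p, and Plaur and Paxip1 the largest falls among the labelled genes.

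Among the 12 largest rises, 2 were regulators of G protein signalling: Rgs18 rose by 2.09 (SE 0.30) and Rgs13 by 2.07 (SE 0.24), the latter from near the floor of the array in control. Bst1, an ectoenzyme of bone marrow stroma and B cell precursors, rose from 3.68 ± 0.14 to 5.68 ± 0.22. Receptors and cytokines followed, with Il9r at 8.70 ± 0.21 against 6.74 ± 0.33, Il18r1 up by 1.82 and Il12a, the p35 subunit of interleukin-12, up by 1.64. The annexin Anxa1 rose by 1.93, the B cell gene Vpreb3 by 1.82 and the stress-responsive gene Ndrg1 by 1.79. The scavenger and fatty acid receptor Cd36 rose by 1.66, the NK receptor Klrd1 by 1.83 and the kallikrein Klk1 by 1.77. Adjusted p in limma ran from 1.36e-05 for Bst1 to 0.0409 for Il18r1. Klk1 belongs to a family of close paralogs, which its probes may not separate, and was dim in control at 2.66 ± 0.18.

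The calls of 3 of these 12 were lost when single pools were left out. Klrd1 lost its call without KO pool 1, 2 or 4 or control pool 1, 3 or 4 (adjusted p up to 0.109), Il18r1 without any 1 pool but KO pool 3 (up to 0.114), and Klk1 without any 1 pool but KO pool 1 (up to 0.0916). Klrd1 and Il18r1 were highest in KO pools 1 and 2, at 7.19 and 6.62 and at 6.66 and 6.32, the pools with the highest mean of the T cell markers (6.51 and 6.20). Without those 2 pools adjusted p was 0.238 for Klrd1 and 0.156 for Il18r1; over all alternatives it reached 0.238 and 0.227.

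Of the 12 largest falls, Plaur, the urokinase receptor, fell by 2.82 (SE 0.21) from 7.90 ± 0.36 to 5.08 ± 0.39. Besides Paxip1 they comprised the immunoglobulin constant region gene Ighg3 (-2.52), the semaphorin and VEGF co-receptor Nrp2 (-2.43), Kctd14 (-2.26), Tnfrsf8 (-2.20), the cytokine Il18 (-2.20), Mall (-2.13), the inhibitory receptor Lilrb4a (4.47 in KO against 6.47 in control), the F-box gene Fbxw13 (-1.99), the fibrinogen-like gene Fgl2 (-1.94) and Wfdc17 (-1.92). Il18 was nearly uniform within groups, at 4.97 ± 0.13 in KO and 7.17 ± 0.09 in control. Adjusted p in limma ran from 1.04e-06 for Il18 and Ighg3 to 0.0120 for Wfdc17. The other probe set of Ighg3 differed by only -0.54, and with the mean of both the fall was 1.53. Ighg3, Lilrb4a and Fbxw13 have close paralogs, which the array may not separate. Mall was not called with the T cell marker mean as a covariate or without KO pools 1 and 2. Its differences there were -2.03 and -1.91 (adjusted p in limma = 0.0736 and 0.0907, up to 0.106 over its alternatives). Wfdc17 was not called without KO pools 1 and 2, at -2.07 (adjusted p = 0.0728, up to 0.136 over its alternatives).

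**Figure D2:**
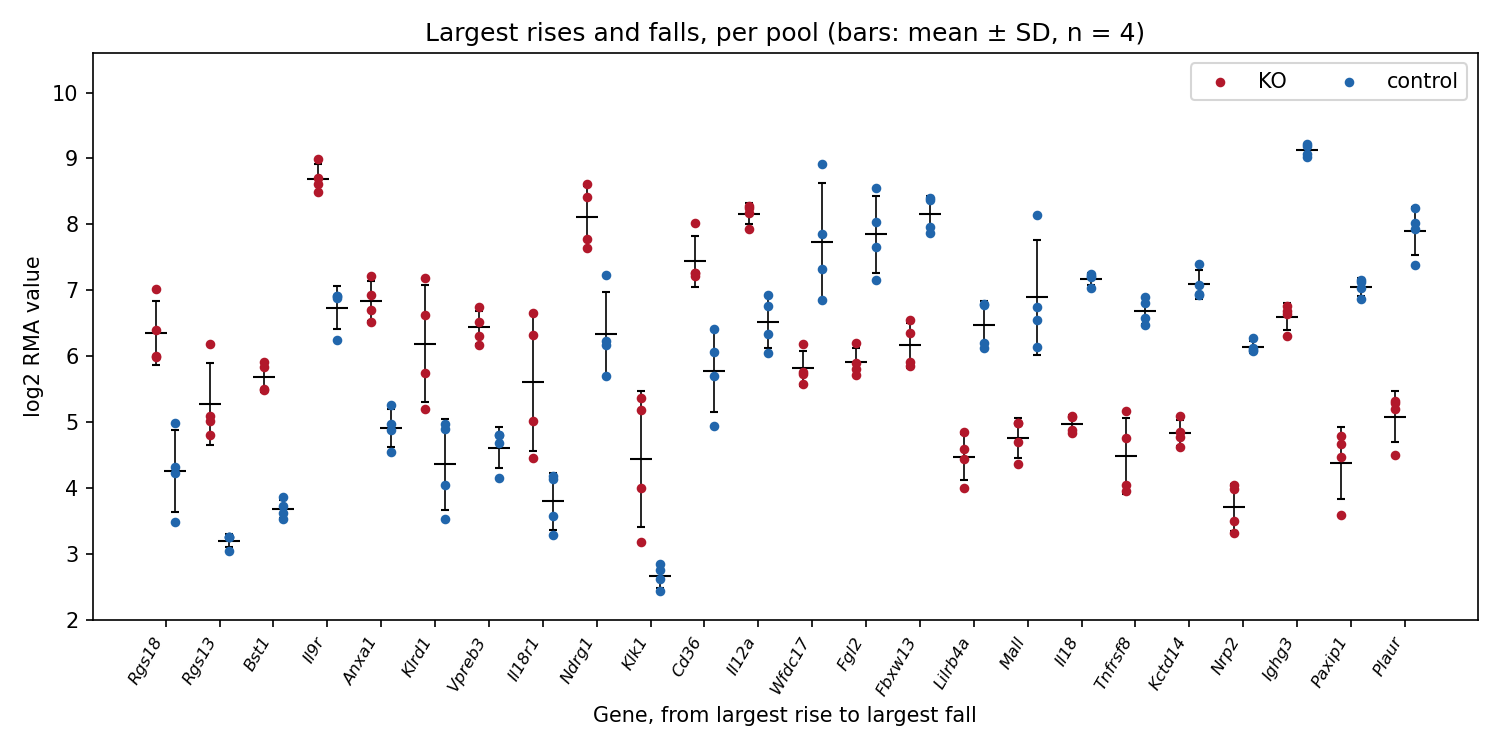
log2 RMA values of the 12 genes with the largest rises and the 12 with the largest falls in each of 4 KO pools (red) and 4 control pools (blue), with mean and SD. No gene's KO and control pools overlap; Klrd1, Il18r1 and Klk1 spread most among KO pools.

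Camera called the B-1a identity list downward at the preset correlation (adjusted p = 0.00202; adjusted p = 0.330 with an estimated correlation), yet its members went apart. By ranks the list was not called (adjusted p = 0.0980; 0.000967 to 0.330 over its alternatives). Of 18 measured members 5 fell and 1 rose over all genes, and 8 passed when adjusted over the list alone. Itgam, which marks B-1 cells of the body cavities, fell by 1.68 (SE 0.16), and the Fc receptor-like gene Fcrl5 fell by 1.39 (SE 0.14). Zbtb32, a transcriptional repressor expressed in B-1 cells, fell by 1.11 (SE 0.15), and Cd36 rose. The other 2 falls, chosen after their values were seen, were Cd9 (-0.60) and Ahnak (-0.38), whose calls were lost without KO pool 2 or control pool 4 for Cd9, and without KO pool 1 or 2 or control pool 2, 3 or 4 for Ahnak (adjusted p up to 0.0675 and 0.0849). Both were also lost with the T cell marker mean as a covariate (0.212 and 0.254, their highest) and without KO pools 1 and 2. Cd5, which defines B-1a cells, and Bhlhe41, a B-1a transcription factor, were also chosen after their values were seen and differed by 0.04 and -0.02, neither past the test.

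Genes of other mature B cell subsets moved both ways. In the follicular B cell list 3 of 12 members rose and 1 fell, with 6 adjusted over the list alone: Vpreb3 rose, the chromatin organiser Satb1 rose by 1.34 (SE 0.16), complement receptor Cr2 (CD21) rose by 0.74 (SE 0.17) and complement regulator Cd55 fell by 0.63 (SE 0.09). In the marginal zone list 2 of 11 rose and 3 fell, with 6 adjusted over the list alone: Pstpip2 fell by 0.99, the Notch target Hes1 by 0.79 and the sphingosine 1-phosphate receptor S1pr3 by 0.53, while Notch2 rose by 0.38. S1pr3 was near the floor in both groups, at 2.54 and 3.06. The list median was 0.07, while its mean was -0.11 and its test pointed downward. Among 15 pan-B cell genes only Cd22, an inhibitory co-receptor of the B cell receptor, was called (-0.59, SE 0.11), also the only one adjusted over the list alone; Blk, Pou2af1 and Blnk differed by -0.24, 0.23 and 0.16 and were not called. The pan-B cell list had a median of -0.04. Camera called none of these 3 lists (adjusted p = 0.0689, 0.402 and 0.272), but called the follicular list upward in 3 of its 20 alternatives. These were the omission of KO pool 3 (adjusted p = 0.0402, the lowest), repeated quantile normalization and an intensity trend with a robust prior; over all its alternatives adjusted p reached 0.330. Fry called the follicular list as moving one way (adjusted p = 0.00782) but not the other 2 (0.127 and 0.408). Cr2 lost its call without any 1 pool but control pool 1, Notch2 without any but control pool 4, Hes1 without any but KO pool 3 or control pool 1, S1pr3 without KO pool 1 or control pool 4, and Cd22 without KO pool 4 or control pool 4; adjusted p then reached 0.114, 0.0870, 0.0754, 0.0556 and 0.0555. All 5 were also lost with the T cell marker mean as a covariate and without KO pools 1 and 2. With the covariate the differences were 0.87 for Cr2, 0.45 for Notch2, -0.51 for Hes1, -0.52 for S1pr3 and -0.59 for Cd22. In the same order, adjusted p in limma reached 0.194, 0.117, 0.248, 0.128 and 0.138 over all alternatives.

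Camera called the B cell receptor signalling list downward at the preset correlation (adjusted p = 0.0294; adjusted p = 0.431 with an estimated correlation). The call was lost without KO pool 2 or 4 or control pool 4 (adjusted p up to 0.102). It was lost in 10 of its 20 alternatives, among them the T cell marker mean as a covariate (adjusted p = 0.182), omission of KO pools 1 and 2 (0.127) and ranks (0.0980), with a range from 0.00967 to 0.431. Of 27 members 4 fell and 1 rose, with 8 adjusted over the list alone. Fcgr2b, the inhibitory Fc receptor of B cells, fell by 1.60 (SE 0.16), Malt1, a paracaspase that links the receptor to NF-kB, fell by 0.78 (SE 0.08), and Cd22 fell, while Rasgrp3, an activator of Ras, rose by 1.22 (SE 0.17). Vav2, chosen after its values were seen, was the other fall (-0.46), lost without any 1 pool but KO pool 3 or control pool 1 (adjusted p up to 0.0879). Cd22 and Vav2 were also lost with the T cell marker mean as a covariate and without KO pools 1 and 2 (up to 0.138 and 0.206).

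Camera called the NF-kB target list upward at the preset correlation (adjusted p = 0.0398; adjusted p = 0.330 with an estimated correlation), not so without KO pool 2 or 3 or control pool 1 or 3 (adjusted p up to 0.0863). The call was lost in 9 of its 20 alternatives, among them the T cell marker mean as a covariate (adjusted p = 0.0937), omission of KO pools 1 and 2 (0.127) and ranks (0.0737), with a range from 0.0147 to 0.330. Of 23 members, 18 had positive differences, 2 rose and 1 fell, and 10 passed when adjusted over the list alone. Gadd45b, a stress-induced gene, rose by 0.98 (SE 0.17) and Nfkb2, the NF-kB p100 subunit, by 0.72 (SE 0.14); the chemokine Ccl4 fell by 0.44 (SE 0.10), and Tnip1 differed by 0.29 without a call, though it was called in 2 of its 20 alternatives. Nfkb2 lost its call without control pool 3 (adjusted p = 0.0520), and Ccl4, dim in both groups, without any 1 pool but control pool 2 (up to 0.104). Without KO pools 1 and 2 neither was called, nor Ccl4 with the T cell marker mean as a covariate; over all alternatives adjusted p reached 0.112 for Nfkb2 and 0.223 for Ccl4.

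Toll-like receptor genes changed in both directions and camera did not call the list (adjusted p = 0.363), which fry called (0.0392 one way, 3.78e-07 in either direction). Of 20 members 2 rose and 5 fell, and 14 passed when adjusted over the list alone, 6 upward and 8 downward. The bacterial lipoprotein receptors Tlr1 and Tlr2 fell by 0.64 (SE 0.11) and 0.51 (SE 0.09) and the kinase Irak2 by 0.48, whereas Tlr3, a receptor for double-stranded RNA, rose by 0.75 (SE 0.13). The others, chosen after their values were seen, were Irak1 (-0.41), Ticam1 (-0.46) and Tlr6 (0.47). Irak1 lost its call without any 1 pool but KO pool 3 or control pool 1, Ticam1 without any but KO pool 4, and Tlr6 without any but KO pool 1 or control pool 3 (adjusted p up to 0.0712, 0.0913 and 0.115). None of the 7 calls held with the T cell marker mean as a covariate or without KO pools 1 and 2. No difference changed sign. With the covariate the differences were -0.63 for Tlr1, -0.44 for Tlr2, -0.47 for Irak2 and 0.83 for Tlr3. Those of Irak1, Ticam1 and Tlr6 were -0.42, -0.38 and 0.57. With the covariate adjusted p was 0.0788 for Tlr1, 0.117 for Tlr2, 0.112 for Irak2 and 0.0549 for Tlr3, and over the alternatives of these 4 it reached 0.117.

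Camera called the migration and adhesion list downward at the preset correlation (adjusted p = 0.00196; adjusted p = 0.330 with an estimated correlation). Of 21 members 5 fell and 1 rose, with 12 adjusted over the list alone. Besides Itgam, the laminin receptor chain Itga6 fell by 0.71 (SE 0.10) and the oxysterol receptor Gpr183, which positions B cells in lymphoid organs, fell by 0.94 (SE 0.16). Cd69, an activation marker that retains lymphocytes in tissue, rose by 1.60 (SE 0.15). The other 2 falls, chosen after their values were seen, were Itgb1 (-0.60), lost without KO pool 4 or control pool 2, 3 or 4, and Ccr9 (-0.37), lost without any 1 pool but KO pool 2 (adjusted p up to 0.0659 and 0.0842). Both were also lost with the T cell marker mean as a covariate and without KO pools 1 and 2 (up to 0.113 and 0.102 over their alternatives). The calls of this list and of the B-1a identity list held with the T cell marker mean as a covariate (adjusted p = 0.000236 and 0.0118) and without KO pools 1 and 2 (0.000455 and 0.00746); over their alternatives adjusted p ran from 0.000236 and 0.000967 to 0.330.

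Camera called the T cell marker list (adjusted p = 3.70e-06; adjusted p = 0.431 with an estimated correlation) and the NK marker list (adjusted p = 2.41e-05; adjusted p = 0.400 with an estimated correlation) upward in KO at the preset correlation. Fry called neither as moving one way (adjusted p = 0.146 and 0.0963), and the pools spread widely. All 15 measured T cell markers and all 11 NK markers had positive differences, with list medians of 0.87 and 0.73. The T cell receptor chains Cd3d and Cd3e stood at 7.42 ± 1.22 and 7.37 ± 1.21 in KO against 5.34 ± 0.81 and 5.16 ± 1.07 in control, and Il7r and Gata3 differed by 2.75 and 0.58; limma called 0 of the 15 T cell markers over all genes, 7 when adjusted over the list alone and 10 at an unadjusted p under 0.05. Of the NK markers, Klrb1c (0.73) and Klrd1 rose, and 7 passed when adjusted over the list alone; the chemokine Ccl5, at 10.3 against 8.02, and Klrk1, differing by 2.02, were not called. Klrb1c lost its call without KO pool 1 or 3 or control pool 1, 3 or 4 (adjusted p up to 0.0946). With the T cell marker mean as a covariate and without KO pools 1 and 2 neither Klrb1c nor Klrd1 was called (up to 0.271 and 0.238). Of the markers followed through the alternatives and not called above, Gata3 was called in 6 of 20, Il7r and Klrk1 in 5 each, Cd3d in 4, and Cd3e and Ccl5 in 2 each. All 6 were called without KO pool 3 (adjusted p = 0.0158 for Klrk1 to 0.0258 for Ccl5), and Il7r without control pool 1 (0.0490); over their alternatives adjusted p reached 0.487, for Ccl5.

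Per pool, the mean of the T cell markers was 6.51, 6.20, 4.53 and 5.01 in KO pools 1 to 4 and 4.76, 4.90, 4.23 and 4.02 in control pools 1 to 4. The mean of the NK markers was 6.01, 5.77, 4.64 and 5.09 in KO and 4.58, 4.75, 4.26 and 3.91 in control. Without KO pools 1 and 2 camera called neither list (adjusted p = 0.233 and 0.127), nor with the T cell marker mean as a covariate (0.779 and 0.269). Neither fit tests the shift. The omitted pools had the highest means while the highest control pools, 1 and 2, were kept, so the difference had to shrink. The covariate removes the signal of the T cell list by construction. Over their alternatives adjusted p ran from 1.24e-11 to 0.779 for the T cell list and from 1.26e-08 to 0.400 for the NK list.

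**Figure D3:**
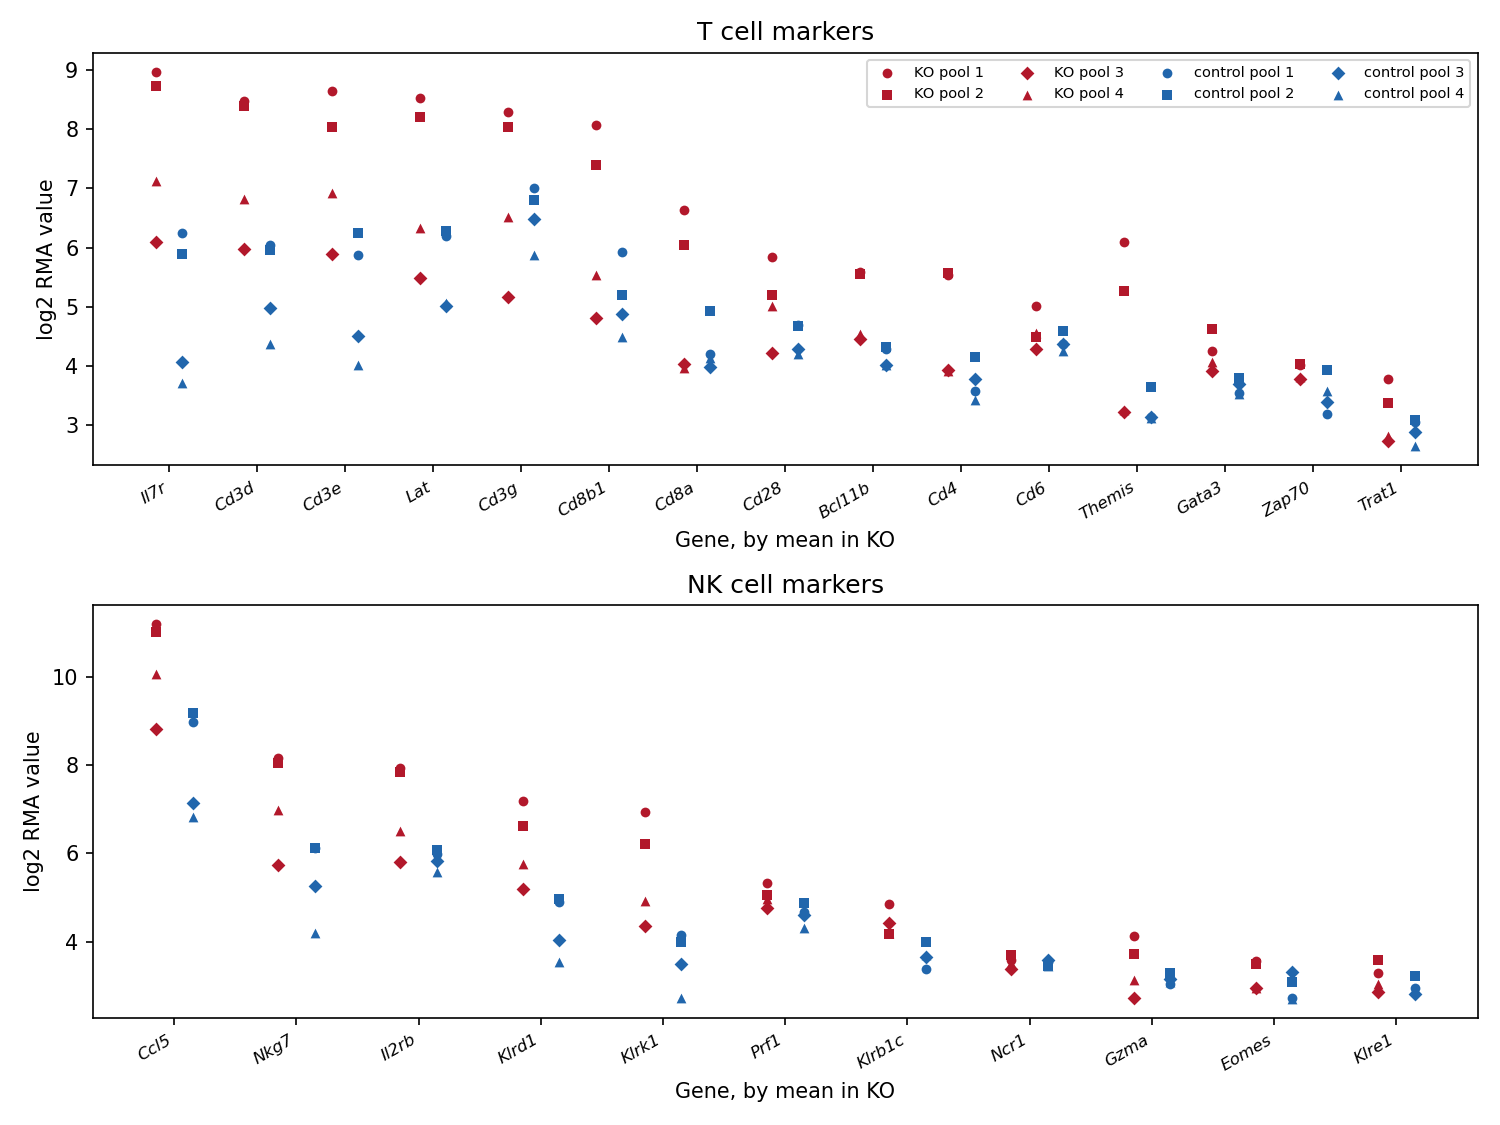
log2 RMA values of 15 T cell markers (upper panel) and 11 NK cell markers (lower panel) in each pool, with KO in red, control in blue and the pool number given by the symbol. KO pools 1 and 2 lie above the other KO pools for Cd3d, Cd3e, Il7r and Ccl5, and control pools 1 and 2 above control pools 3 and 4.

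Single markers of other cells of the peritoneal cavity were not called. No member of the macrophage (20 members), mast cell (11), neutrophil (12), eosinophil (6), dendritic cell (9), mesothelium and fibroblast (12) or erythroid (2) lists was called by limma over all genes or adjusted over the list alone, with 3, 0, 1, 1, 5, 2 and 0 members at an unadjusted p under 0.05. Camera called none of the 6 tested lists (adjusted p from 0.111 to 0.784), although it called the mast cell list without control pool 1 (adjusted p = 0.0191; up to 0.945 over its alternatives) and the dendritic cell list without control pool 2 (0.0499; up to 0.599). Of all pools, control pool 1 had the highest means of the mast cell and macrophage lists (3.76 and 5.42). Fry called the dendritic cell and the mesothelium and fibroblast lists as moving one way (adjusted p = 0.0392 and 0.0377). The macrophage marker Adgre1 differed by -0.76 and the dendritic cell gene Ccr2 by 1.07, neither past the test. Adgre1 was called in 2 of its 20 alternatives, among them the T cell marker mean as a covariate (-1.21, adjusted p = 0.0385; up to 0.335 over its alternatives). Ccr2 was called in 1 of 20, and its difference all but vanished with the covariate (-0.06) and shrank without KO pools 1 and 2 (0.23). Of the 9 immature B cell markers limma called none over all genes, 4 had an unadjusted p under 0.05 and 3 passed when adjusted over the list alone, Il7r (shared with the T cell list), the terminal transferase Dntt (0.47) and Lef1 (0.63), the last differing by 0.10 with the T cell marker mean as a covariate; camera called this list upward (adjusted p = 0.0462; adjusted p = 0.330 with an estimated correlation), but not without KO pool 1 or 2 or control pool 1, 3 or 4 (adjusted p up to 0.0996). That call was lost in 11 of its 19 alternatives, also with the T cell marker mean as a covariate (adjusted p = 0.182) and without KO pools 1 and 2 (0.130), with a range from 0.0118 to 0.330. Of the 4 sex-linked genes limma called none, and 0 had an unadjusted p under 0.05; the female-specific Xist was bright in both groups, at 11.3 and 11.5, and the group means of the Y-linked Kdm5d, Uty and Eif2s3y lay between 2.27 and 2.53.

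In the plasma cell and secretory list the immunoglobulin joining chain Jchain rose by 1.49 (SE 0.14) and the endoplasmic reticulum chaperone Fkbp11 fell by 0.49 (SE 0.09), the only 2 calls of 20 members (7 adjusted over the list alone). The transcription factor Irf4 and the chaperone Dnajb9 differed by -0.34 and 0.35 without a call, though they were called in 2 and 3 of their 20 alternatives. In the interferon list Rtp4 rose by 1.16 (SE 0.13) and Stat2 fell by 0.62 (SE 0.11), the only 2 calls of 21 (3 adjusted over the list alone). The calls of Fkbp11 and Stat2 were lost with the T cell marker mean as a covariate (adjusted p = 0.176 and 0.122, their highest), without KO pools 1 and 2 (0.149 and 0.0832) and without moderation of the variance, and that of Fkbp11 also with a replicate block. Camera called neither list (adjusted p = 0.272 and 0.110), but called the interferon list without control pool 1 (adjusted p = 0.0476; up to 0.330 over its alternatives). Fry called the interferon list as moving one way (adjusted p = 0.0377).

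Metabolic genes changed singly. Pdk1, a pyruvate dehydrogenase kinase, rose by 0.80 (SE 0.11) and the phosphofructokinase Pfkp by 0.48, while Pfkfb3 fell by 0.53. This made 2 rises and 1 fall among 14 glycolysis genes (5 adjusted over the list alone). Of 22 lipid handling genes 4 rose and 1 fell (7 adjusted over the list alone): Cpt1a, the entry enzyme of mitochondrial fatty acid oxidation, rose by 0.78 (SE 0.12), Cd36 and the acyl-CoA dehydrogenase Acadl (0.40) rose, as did the lipase Pnpla2 (0.54), chosen after its values were seen, and the cholesterol exporter Abca1 fell by 1.05 (SE 0.19). Limma called none of the 22 oxidative phosphorylation genes, 1 of which had an unadjusted p under 0.05. Camera gave adjusted p = 0.126, 0.461 and 0.334 for the 3 lists, and fry 0.0392, 0.0392 and 0.194 for a move one way. Pfkp lost its call without KO pool 1 or 2 or control pool 3, Pfkfb3 without any 1 pool but control pool 1, Acadl without KO pool 1 or 2 or control pool 2, 3 or 4, and Pnpla2 without any but KO pool 4; adjusted p then reached 0.0577, 0.117, 0.0733 and 0.103. Without KO pools 1 and 2 these 4 and Abca1 were not called, nor with the T cell marker mean as a covariate, except Pfkfb3; over all alternatives adjusted p reached 0.263, for Pnpla2.

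Camera called none of the remaining lists. In the MLL3 and MLL4 complex list limma called 0 of 9 members, with 3 at an unadjusted p under 0.05; its methyltransferase Kmt2c differed by -0.33 (SE 0.08, adjusted p = 0.0501) and was the only one to pass when adjusted over the list alone, and Kmt2d differed by -0.25. Kmt2c was called in 7 of its 20 alternatives, with differences from -0.37 to -0.30 and adjusted p up to 0.248. The list gave adjusted p = 0.272 by camera and 0.0392 by fry. Among apoptosis regulators the pro-apoptotic Bcl2l11 rose by 0.39, 1 of 19 members by either count, and lost the call without any 1 pool but KO pool 3 (adjusted p up to 0.101). Among immediate early genes the phosphatase Dusp2 rose by 0.46, 1 of 20 members by either count, and lost the call without KO pool 1 or 4 or control pool 3 (adjusted p up to 0.0539). With the T cell marker mean as a covariate and without KO pools 1 and 2 neither was called (up to 0.294 and 0.186). Limma called none of 21 DNA break response genes over all genes, 3 had an unadjusted p under 0.05 and 1 passed when adjusted over the list alone, Mad2l2 (0.31), called over all genes in 4 of its 20 alternatives. Camera gave adjusted p = 0.886, 0.591 and 0.347 for these 3 lists. In the lists of mitosis (25 members), DNA replication (25), p53 targets (20) and ribosome biogenesis (18), 0 genes were called by limma by either count and 2, 3, 5 and 1 had an unadjusted p under 0.05; camera gave adjusted p = 0.754, 0.538, 0.632 and 0.537. The mitosis list turned when KO pool 4, whose list mean of 5.33 lay above all other pools, was left out: it was then called downward (adjusted p = 0.000967). Without KO pools 1 and 2 it was called upward (adjusted p = 0.0381; up to 0.953 over its alternatives). Median and test differed in sign for the DNA replication list (median 0.02, mean -0.04, test downward) and the apoptosis list (median -0.02, mean 0.02, test upward). With an estimated correlation none of the 30 lists was called by camera and 4 had an unadjusted p under 0.05, while fry called 13 as moving one way and 20 as changing in either direction. Of the 7 lists called by camera at the preset correlation, fry called all but the T cell and NK cell lists as moving one way.

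**Figure D4:**
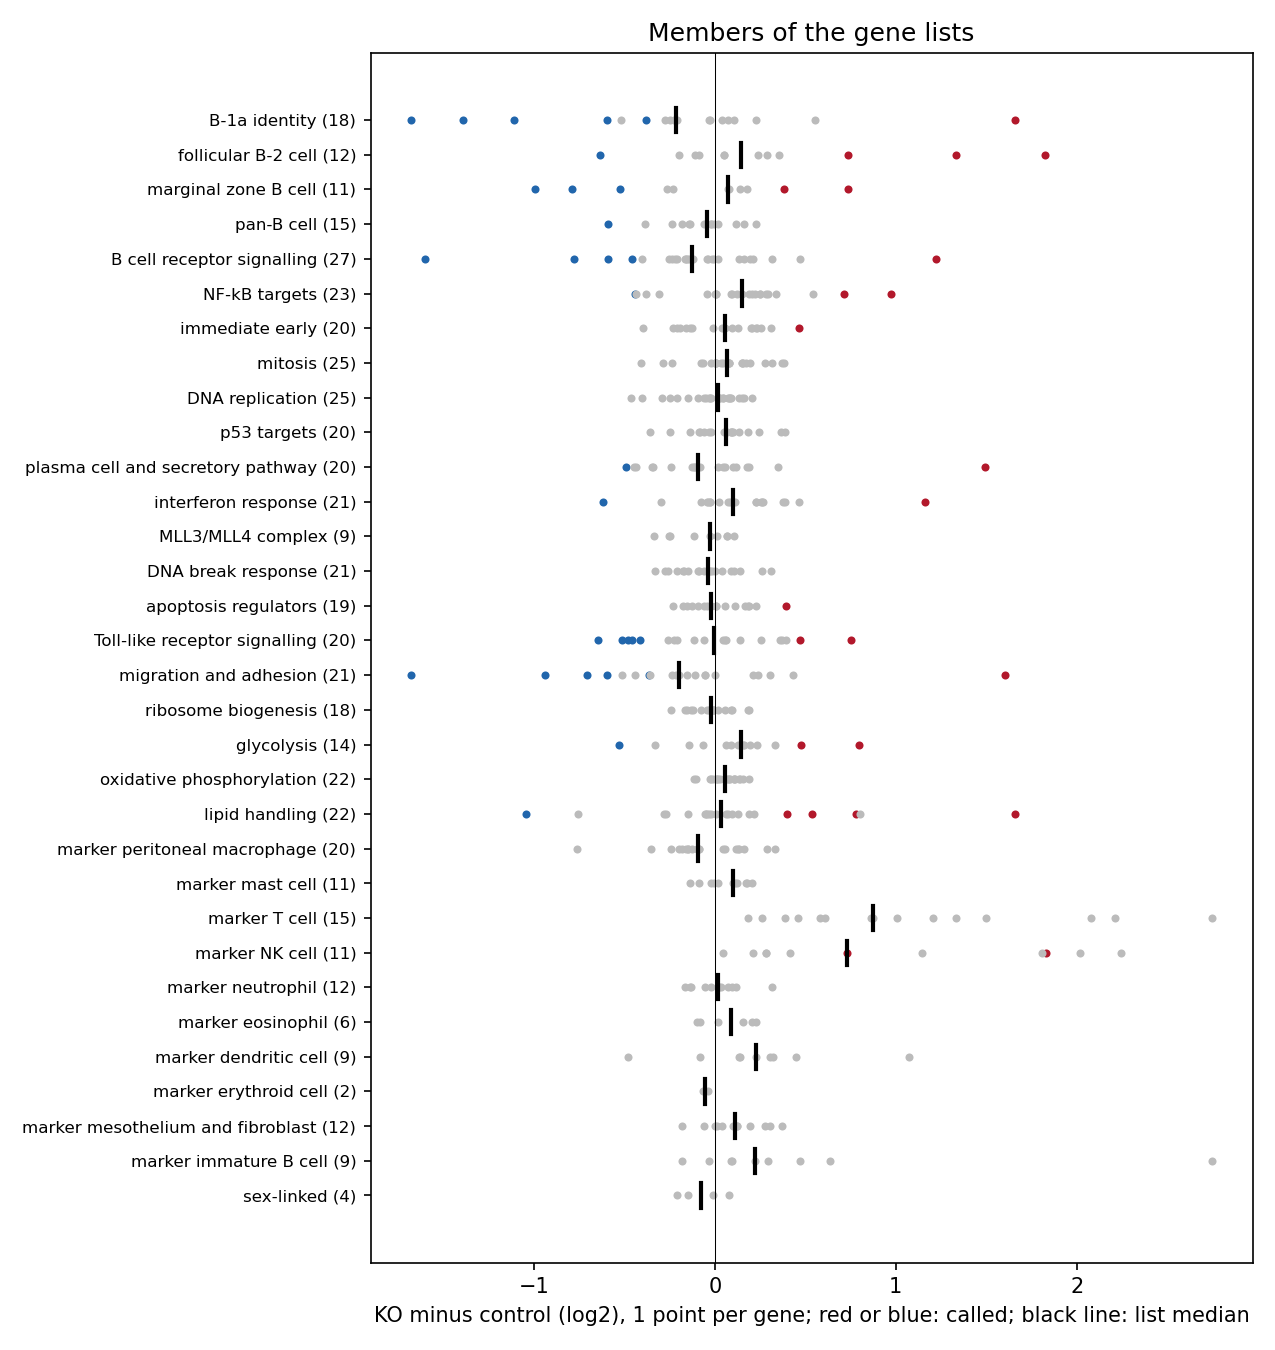
Difference between KO and control (log2, horizontal) of each measured member of the 32 gene lists, 1 point per gene, with called genes in red (higher in KO) or blue (lower) and others in grey; black lines are list medians and numbers in brackets are members measured. The T cell and NK cell marker lists lie to the right, with medians of 0.87 and 0.73, and the B-1a identity list has a median of -0.22.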

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

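The tests of the T and NK cell markers, of the genes higher in KO and of the B-1a genes were chosen after those results were seen; the counts over other splits of the arrays were fixed beforehand.

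In 350 groups of 4 pools (the named genes, the list examples and the list means), 23 had a pool far from the other 3, where chance gives about 17.5, or 1 in 20. Of KO pool 4, Cd36 stood at 8.02 against 7.21 to 7.27 in the other KO pools, Plaur at 4.50 against up to 5.32, Dpy30 at 6.44 against 6.09 to 6.12, Uqcrc2 at 9.22 against 8.99 to 9.01, Hdc at 3.0 against 3.40 to 3.48 and the mean of the mitosis list at 5.33 against 4.29 to 4.41. Satb1 stood at 5.92 in KO pool 1 against 5.29 to 5.39, Ear10 at 2.04 in KO pool 2 against 2.21 to 2.23, and the mean of the B cell receptor signalling list at 8.53 in KO pool 3 against 8.46 to 8.47. Of control pool 1, Itgam stood at 7.70 against 7.09 to 7.18 in the other control pools, Junb at 6.56 against 6.62 to 6.64, Uhrf1 at 5.36 against 6.03 to 6.07, Slc4a1 at 3.82 against 4.21 to 4.26 and the mean of the Toll-like receptor list at 7.20 against 7.17 to 7.18. Of control pool 2, Il9r stood at 6.24 against 6.88 to 6.92, Hes1 at 5.52 against 5.15 to 5.18, Gpr183 at 9.27 against 8.83 to 8.88, Abca1 at 6.61 against 7.39 to 7.45 and the mean of the p53 target list at 5.29 against 5.34 to 5.35. Of control pool 3, Rgs13 stood at 3.04 against 3.25, Fcrl5 at 8.35 against 8.88 to 8.92 and Apaf1 at 6.71 against 6.43 to 6.48, and in control pool 4 the mean of the neutrophil list at 2.84 against 2.88 to 2.89.

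Chance is an unlikely source of the gene counts, although 1 split of 35 is the fewest this design allows. The other splits mix the genotypes, so the genotype difference widens the spread within their groups and lowers their counts. Of the 35 splits of the 8 arrays into 2 groups of 4, the real one included, 1 called as many as 797 genes, and the highest other split called 1. The same held for the 331 genes higher and the 466 lower in KO, with 1 split of 35 each and a highest other count of 1. Chance cannot be called unlikely for the number of lists: 3 of the 35 splits called as many as 7 lists, and the highest other count was 7. Only the split of KO pools 1 and 3 with control pools 3 and 4 called 0 lists. Splits with 2 KO and 2 control pools in each group, which balance the genotypes, called 0 to 5 lists. Being called at the preset correlation therefore does not by itself set a list apart from chance.

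Camera called the T cell and NK cell marker lists upward in KO at the preset correlation, but not with an estimated correlation (adjusted p = 0.431 and 0.400). Without KO pools 1 and 2 it called neither (0.233 and 0.127, up to 0.779 and 0.400 over their alternatives). Those pools had the highest means of these markers, so leaving them out had to shrink the difference. Limma called 0 of the 15 T cell markers, 10 of which had an unadjusted p under 0.05, and 2 of the 11 NK markers. RNA of T and NK cells sorted along with the B-1a cells, in amounts that differ between pools, is a candidate source. The gates of the sort are not given in the sources used here, so how far it removed such cells is not known. Within groups the markers varied together, with an estimated correlation between members of 0.787 in the T cell list and 0.665 in the NK list, but the mitosis list reached 0.734, so that shared variation does not single out foreign cells. The highest array values among the markers were those of Ccl5, Il7r, Cd3d and Cd3e (KO means 10.3, 7.73, 7.42 and 7.37), which as values of different probe sets do not rank abundance. Transcription of these genes in Paxip1-deficient B-1a cells cannot be told apart from sorted-along cells. The pools did not decide it: 3 of the 4 KO pools had a mean of the T cell markers above the highest control pool and 1 did not. By number, each KO pool lay above its control pool (pool 3 at 4.53 against 4.23). Whether the numbers pair the pools is not given in the sources used here. In control pools 10 of the 15 T cell markers and 5 of the 11 NK markers had array values above the median gene. As values of different probe sets these are no measure of expression there. Of the T cell markers 1, Il7r, is also on the immature B cell list.

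The genes higher in KO might likewise come from T and NK cell RNA. The slope on the T cell marker mean within groups, times the group difference of 1.09, predicted a median share of -0.0232 of the rise. The bootstrap interval over genes was -0.0480 to -0.00269, and the share was at least 0.5 for 6 of the 331 genes. These shares cannot decide whether such RNA is the whole cause. A call needs a small spread within groups, and limma called 0 of the 15 widely spread T cell markers. Low shares among called genes were therefore partly built in by their selection. The interval also leaves out the error of each gene's slope. With the T cell marker mean as a covariate the difference was 0.69 for Klrd1 (adjusted p = 0.126; 0.00234 to 0.238 over its alternatives) and 0.62 for Il18r1 (adjusted p = 0.0222; 0.00558 to 0.227).

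Itgam, Fcrl5, Zbtb32, Cd9 and Ahnak fell by a median of 1.11 (log2). Fewer B-1a cells and more of another B cell type in the KO sorts might lower them and cannot be told apart from other sources. The median difference over all 17 members of the B-1a list, Cd5 aside because the cells were sorted as B-1a, was -0.225 (bootstrap interval -0.520 to 0.0707), and Cd36 rose. Follicular B cells in the KO sorts likewise cannot be told apart by Cr2, Fcer2a, Klf2 and Ccr7, of which 2 were lower in KO. None of these falls was called. These genes were picked from the follicular list, of whose 12 members 8 had positive differences. Adjusted over the list alone, 5 members rose and 1 fell. Fry called the list as moving one way (adjusted p = 0.00782), while camera did not call it (adjusted p = 0.0689). The whole list thus leaned upward more than the picked genes. An effect of the genotype within B-1a cells stays open as a hypothesis.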

How the results depend on the processing

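The fits with the T cell marker mean as a covariate and without KO pools 1 and 2 were chosen after the data were seen. Of the 24 named genes, 15 kept direction and call in every alternative run; of their 479 values 436 kept both, 43 lost the call and 0 reversed. Klrd1 and Il18r1 lost it in 11 alternatives each, Klk1 in 10, Wfdc17 in 4, Mall in 3, and Rgs18, Ndrg1, Cd36 and Fgl2 in 1 each. Paxip1 stayed called in all 20 of its alternatives (-2.95 to -2.40). Of 46 other called list members, 12 kept the call throughout. Without 1 pool at a time, 479 to 758 genes were called, 196 to 296 higher and 274 to 462 lower, and 4 to 8 lists; fewer arrays were then tested. Without moderation of the variance 303 genes were called (127 higher, 176 lower), with the T cell marker mean as a covariate 312 (148 and 164), and without KO pools 1 and 2 320 (137 and 183). At least a 1.5-fold difference left 429 (176 and 253) and adjusted p under 0.10 gave 1202 (533 higher). Whether same-numbered pools share more than a number is not given in the sources used here. Their deviations correlated by 0.036 to 0.11, and 2 of 4 KO arrays correlated best with the control array of their own number. In both genotypes pools 1 and 2 had higher T cell marker means than pools 3 and 4, so more may be shared. The replicate block gave 666 genes (291 higher, 375 lower). Instead of 7 lists, 4 were called without genes below percentile 25, 0 with an estimated correlation, 3 with ranks, 2 with the covariate and 3 without KO pools 1 and 2. The mitosis list was called downward without KO pool 4 (adjusted p = 0.000967; up to 0.899 without another pool), whose high mitosis mean had set its direction, but upward without KO pools 1 and 2 (0.0381). The T cell list turned with its own mean as covariate (adjusted p = 0.779), which removes its signal by construction. For the other changes the cause was not tested. Signal near background limits dim genes.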

Other observations

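The genes of the next 2 paragraphs, the test of variable segments and the test of genes linked to Paxip1 were chosen after their values were seen; the restricted test of neighbouring genes was fixed before its result was seen. Of the 40 called genes outside the lists and the naming rule that were followed, 16 kept the call in every alternative.

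The following called genes lie outside the fixed lists and stand for no tested group. Il6st, the gp130 chain shared by receptors of the interleukin-6 family, fell by 1.64 (SE 0.12, limma, adjusted p = 5.50e-05) and its partner Lifr fell by 1.55 (SE 0.18). The ligands of PD-1, Cd274 and Pdcd1lg2, fell by 0.83 and 0.89 (not called with the T cell marker mean as a covariate or without KO pools 1 and 2), the inhibitory receptors Siglecg and Pirb by 0.83 and 0.81, and Tnfsf4 (OX40 ligand) by 1.77. The class II transactivator Ciita fell by 0.73 (SE 0.10). The class II pathway genes H2-DMb1 and Rfx5 fell by 1.13 and 0.41 and were called (limma, adjusted p = 0.0146 and 0.0386). Neither was called with the T cell marker mean as a covariate or without KO pools 1 and 2. Rfx5 was also lost without any 1 pool but control pool 3. H2-Aa and H2-Ab1, class II genes on the pan-B cell list, differed by -0.38 and -0.02 and were not called. Spry2 and Dusp6, feedback inhibitors of the MAP kinase pathway, rose by 1.29 (SE 0.09) and 1.19 (SE 0.24), the latter lost without any 1 pool but KO pool 3 or control pool 1 (adjusted p up to 0.0713), and also with the covariate (0.217, its highest). The clone 2210414B05Rik had the largest difference of any symbol, a rise of 3.08 (SE 0.16) from 3.19 in control.

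Of 25 immunoglobulin variable segments tested, 9 were called, 7 higher and 2 lower, against 3.61% of all located genes (Fisher's exact test, two-sided, p = 1.21e-07; genes are not independent replicates). Without 1 pool at a time 5 to 9 segments were called, the fewest without KO pool 2, and 5 to 7 of the 9 kept their call. With the T cell marker mean as a covariate 3 were called (2 of the 9), without KO pools 1 and 2 3 (all among the 9), and without moderation of the variance 2. The calls were lost more than the differences: with the covariate that of Iglv1 was -0.65 (adjusted p in limma = 0.0622, its highest). Igkv8-30 kept its call in every alternative and differed by 1.39 with the covariate. Igkv8-30 rose by 1.23 (SE 0.12), Iglv1 fell by 0.67 (SE 0.11), and the joining segment Igkj1 rose by 0.69 (SE 0.09). Variable segments resemble one another, and cross-hybridisation between them was not tested.

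Called genes lay next to each other more often than under shuffled positions. Among 21994 located genes, 48 neighbouring pairs changed in the same direction against a median of 15 in 2000 shuffles within chromosomes (permutation, one-sided, p = 5e-04, the smallest these shuffles give), and 20 pairs changed in opposite directions against 14 (permutation p = 0.08). Overlapping or related transcripts might produce such pairs. Among protein-coding neighbours that do not overlap and have unlike names, 28 same-direction pairs remained against a shuffled median of 10 and a maximum of 21 (permutation p = 5e-04). Of these 28, 6 still join genes judged to be related, such as Cd274 with Pdcd1lg2 or Pirb with Gm15448, which leaves 22 and argues against relatedness as the whole cause. Other examples are Chchd10 with Vpreb3 (0.83 and 1.82) and Leprotl1 with Saraf (0.94 and 1.23). The 6 pairs were picked after they were seen, and others may be related too. The shuffles also moved calls to genes near background, so any clustering of expressed genes was not accounted for. Shared regulation of neighbours stays open as a hypothesis.

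Alleles of genes linked to the floxed locus could differ between the genotypes. Paxip1 lies on chromosome 5, and of the 793 other called genes with a location 54 lie there, or 6.81% (exact binomial interval 5.16 to 8.79), against 5.73% of all located genes. This share argues against alleles of linked genes, changing only those genes, as the whole cause of the 797 calls. It cannot tell whether such alleles act on genes of other chromosomes. Genes close to Paxip1 were not examined apart from the rest of the chromosome, nor which of the genes named above lie near it. Single calls on that chromosome therefore stay open.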
